A study of Caenorhabditis elegans with 2 samples.

How the data were processed

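APTF-2 binding was measured by ChIP-seq with an anti-GFP antibody in whole C. elegans young adults of 61.5 h, from 2 biological replicates with 1 technical replicate each. Per the labels, the animals were synchronised as starved larvae after bleaching, carried a CRISPR insertion of a TY1, EGFP and 3xFLAG tag at aptf-2, and their chromatin was sonicated to 200 to 800 bp. Both replicates form 1 group, taken from the labels. They are labelled as separate biological replicates.

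Per the README text deposited with each sample, the authors derived their peak lists on assembly ce11 from the alignments of 1 or both replicates and a further file that their tracks of fold change over control also draw on. The lists are named there as ranked or thresholded by IDR, which measures how reproducibly a peak ranks in a pair of lists. The peak caller, the aligner and their versions are not given in the sources used here. The deposited signal value of a peak is a score of the authors' caller with no stated scale, and the deposited IDR score runs to 1000. The deposited −log10 columns hold the q value and the global IDR. In the ranked lists every listed peak was found again, with IDR scores of 830 or more, which stands for a global IDR of 0.01 or less. Thresholded lists draw on 1 more file, whose content is not given in the sources used here. The signal tracks named there were not analysed here. The list called conservative served as the main list (892 peaks). The other thresholded list from both replicates had 832 peaks, and the replicates had 350 and 403. The ranked list behind the main one had 94866 peaks. That list also gives each peak the signals of 2 inputs, meaning the peak lists paired for IDR and not control DNA. These columns carry no replicate names. Of the values in the first, 54.2% occurred in replicate 1's own ranked list and 1.82% in that of replicate 2. For the second these shares were 1.91% and 53.2%, so the inputs were read as replicates 1 and 2. Beyond this, the columns were used only to see which peaks share the same inputs and how far the inputs differ. No read counts were analysed, so depth per replicate is unknown and no adjustment for it was made here. A peak caller finds more peaks in deeper libraries, and pooling replicates raises the signal, so signals of different lists were not compared. Whole animals mix all tissues, so a site bound in few cells can be missed. The control library was not analysed here.

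Positions were read as ce11, which is WBcel235, and the check of peak ends against chromosome lengths passed for all 6 chromosomes. Genes came from Ensembl release 115, with 19973 protein-coding genes and 29314 protein-coding transcript starts on the 6 nuclear chromosomes. Scripts used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, matplotlib 3.10.9 and BLAST 2.17.0. The summit is the point source given for each peak. A gene was bound if a summit lay from 1000 bp upstream to 200 bp downstream of any of its protein-coding transcript starts. Random placement drew 1000 sets of positions with the observed number per chromosome. Motifs were searched on both strands in 201 bp windows at the summit and 500 bp away on a seeded random side, and compared with exact McNemar tests. Gene lists were tested with Fisher's exact test against all other protein-coding genes, and non-coding classes by random placement within 200 bp. Families of 24 motifs, 24 lists and 6 classes were each adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The symbol efn-1 in the ventral enclosure list matched no gene; its other name, vab-2, stood in the list already. Genes with neighbouring or divergent starts can share a summit, so bound genes are not independent of each other. Tests across peaks treat peaks, not animals, as units, and their p-values say nothing of the spread between further replicates.

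The named sites follow a rule fixed before the data were examined. It takes the 25 strongest main-list peaks in a promoter window with a listed peak in both replicates, and the 5 strongest without a protein-coding start in the window. It adds the AP-2 family genes, up to 4 bound genes of highest signal per list and the 2 strongest peaks of each class that passed. Alternatives covered the other list, each replicate alone, the stronger 50% of the main list, peaks found in both replicates, other windows, motif forms, controls and gene assignments. After the data were seen, 3 more were added: 1 peak per pair of replicate peaks, windows with a single copy in the genome, and GC-matched controls for the motif scan. A copy was a BLAST match of 100 bp or more at 90% identity or more to the summit window. The tests were run on simulated lists of 892 peaks. For the promoter share, a planted share of 55.8% came back as 58.7%, and 2 of 20 random lists had a p under 0.05. In the AP-2 test 60 palindromes were planted and counted with the same pattern, so their full recovery was fixed in advance. It says nothing of the power to find a small difference. Of 20 random lists, 2 had a p under 0.05 in this test. In the gene list test 30 planted genes gave 33 bound genes of the list, and 1 of 20 random lists gave any call.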

Results

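APTF-2 is a member of the AP-2 family of transcription factors of the nematode Caenorhabditis elegans, known for its part in shaping the embryonic epidermis. Its binding was mapped by ChIP-seq, in which chromatin is sheared, precipitated with an antibody and sequenced. The worms carried the endogenous aptf-2 gene fused to EGFP, and the precipitation used an anti-GFP antibody. Chromatin came from whole young adults 61.5 h old, in 2 biological replicates of 1 group. The design has no second condition, and no library without the tagged protein was analysed here. The files are peak lists, so sequencing depth is unknown, and the intervals given below cover counting of peaks or genes only. The main list, made by the authors from both replicates under a limit on the irreproducible discovery rate (IDR), held 892 peaks with a median width of 296 bp. The separate lists held 350 peaks for replicate 1 and 403 for replicate 2. All positions are on assembly ce11. Signal is the score of the authors' peak caller, whose scale is not stated, and its size is compared within a list only.

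The first comparison asked whether both replicates placed APTF-2 at the same sites. Of the replicate 1 peaks, 238 of 350 (68%, 95% Wilson interval 62.9 to 72.7%) overlapped a replicate 2 peak by at least 1 bp. In the other direction, 237 of 403 replicate 2 peaks (58.8%, interval 53.9 to 63.5%) overlapped a replicate 1 peak. Randomly placed peaks of equal width shared 0.801 and 0.759 peaks on average and at most 5, which gave a one-sided permutation p of 0.001 in each direction, the smallest that 1000 placements allow. Over 232 pairs of shared peaks, signal rose together in both replicates, with a Spearman rho of 0.815 and a Pearson r of 0.884 on log10 signal. Each had a two-sided permutation p of 1e-05, the smallest that 100000 permutations give. These are correlations across peaks, which are not independent replicates. Without the 2 peaks farthest from the median of replicate 1, rho was 0.81 and r was 0.872. Of the 892 main-list peaks, 236 (26.5%) overlapped a peak in the own thresholded lists of both replicates and 430 (48.2%) in neither of these lists. Median signal was 188.6 in the former and 87 in the latter. The phrase peaks found in both replicates stands for these 236. The longer ranked lists did not enter this count, so it does not show that a replicate had no peak at the 430. In the ranked list behind the main list, each of the 892 peaks was paired with a peak signal from both inputs, read as the replicates.

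**Figure D1:**
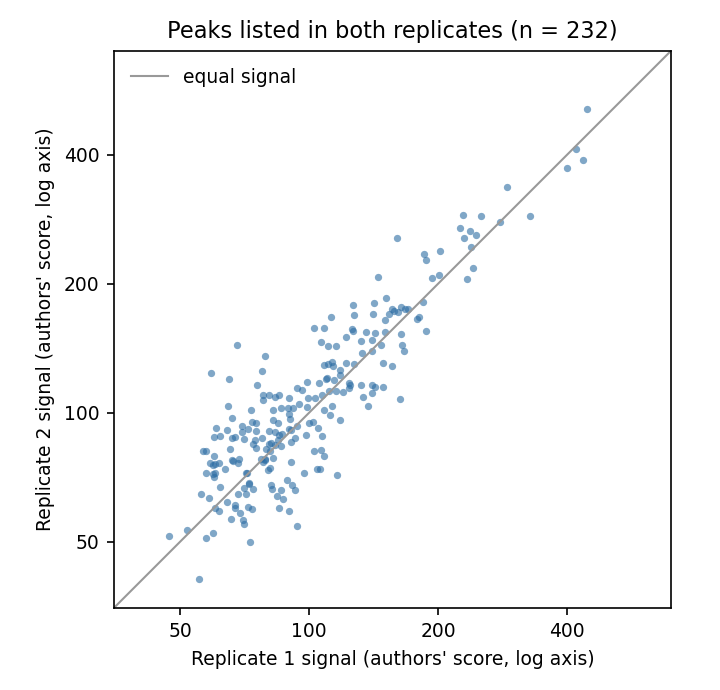
Signal of the 232 peaks listed in both replicates, with replicate 1 on the horizontal and replicate 2 on the vertical log axis, in the units of the authors' peak score. Each point is 1 peak and the line marks equal values. Peaks with a higher signal in 1 replicate had a higher signal in the other, with a Spearman rho of 0.815.

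The second question was where in the genome the sites lay. APTF-2 summits were most frequent per Mb on chromosome II (12.1), followed by I (11.3) and III (10.9), and less frequent on IV (7.95), X (6.43) and V (6.36). The counts departed from chromosome length (chi-square of 63, p = 2.89e-12). X held 114 summits, 0.683 times the density of the autosomes (exact binomial p = 9.03e-05). In the list of replicate 2 alone this ratio was 0.768 and no longer passed (exact binomial p = 0.0672). The central 50% of the autosomes held 431 of 778 autosomal summits (55.4%, interval 51.9 to 58.9%, exact binomial p = 0.0029), but this excess did not pass in either replicate's own list.

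Summits gathered at the starts of protein-coding genes. They fell within 1000 bp upstream to 200 bp downstream of a protein-coding transcript start in 493 of 892 peaks (55.3%, interval 52 to 58.5%). Random placement on the same chromosomes gave 26.1% (SD 1.47), so that the share was 2.11 times that of chance (two-sided permutation p = 0.002, the smallest that 1000 placements allow). For 483 summits the nearest start had the summit in its window. Of these, 436 (90.3%) lay upstream, against 78.8% of random positions chosen in the same way and at most 84.5% in any of 100 placements. The median position relative to the start was -213 bp, with quartiles of -408.5 and -105 bp. Of the 399 summits outside the promoter windows, 43 (10.8%) lay in coding exons, against 26% of random positions outside them. Another 9 lay in untranslated exons (2.26% against 3.71%), 133 in introns (33.3% against 37.6%) and 214 elsewhere (53.6% against 32.7%).

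The strongest main-list peak was on X at 9883873 to 9884165, between genes, 248 bp upstream of a start of mrp-4 (WBGene00003410), an ABC transporter gene. Its signal was 949.6 in the list from both replicates, 446 in replicate 1 and 512 in replicate 2. The next lay on III at 5406345 to 5406666, in an intron and 492 bp upstream of a start of Y32H12A.8 (WBGene00021316), with a signal of 841. Y69H2.7 (WBGene00013482) followed with a peak on V at 18689739 to 18690029, 94 bp upstream of its start, and a signal of 818. On the same chromosome 3 of the 25 strongest promoter peaks lay close together, at T10C6.7 (16031648 to 16031905, signal 779.6), T10C6.16 (16033636 to 16033848, 544) and T10C6.10 (16036264 to 16036435, 351). Others of the 25 lay upstream of mog-4 (II, 14561745 to 14561958, 525), a splicing helicase gene, and of cdc-25.3 (III, 8918071 to 8918289, 504), which encodes a CDC25-type phosphatase. The chloride channel gene clh-3 (II, 7226221 to 7226413) had a signal of 499. The replication protein gene rpa-2 (I, 4769552 to 4769745) had 409.8, and vps-39 (V, 14038799 to 14038966), a gene of endosome to lysosome traffic, had 366. At czw-1 (IV, 7947029 to 7947219), a gene of the kinetochore, the signal was 363, and the summit window had 84 similar copies in the genome, itself included. With the window itself counted, similar copies numbered 8 at mog-4, 8 at rpa-2, 20 at vps-39, 2 at T10C6.7, 3 at T10C6.16 and 2 at T10C6.10. They numbered 20 at mtcu-2, 7 at F29G9.1 and 5 at VH15N14R.1, which also belong to the 25. The other windows of the 25 had no similar copy elsewhere. The remaining peaks of the 25 had signals from 341 to 611, the highest at F14D7.2 (V, 14293821 to 14294134).

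Among peaks with no protein-coding start in the window, the strongest lay between genes on X at 5518476 to 5518721, 1441 bp upstream of T23F2.5, with a signal of 630.2. The next was on V at 13647698 to 13647967, in an intron 580 bp downstream of a start of H37A05.4, with 560.2. A pair lay near K08F11.1 on IV, at 4727927 to 4728149 (498) and at 4725505 to 4725684 (403), and the last near C46C2.7 on IV at 9196334 to 9196493 (327). The summit windows near K08F11.1 had 8 similar copies each and that near C46C2.7 had 9, the windows themselves included.

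None of the 4 AP-2 family genes was bound, aptf-2 itself included. The nearest main-list summit lay 34886 bp from the start of aptf-2 (WBGene00013383, IV, 13413555 to 13416051), 106941 bp from aptf-1, 32767 bp from aptf-3 and 29561 bp from aptf-4. The AP-2 palindrome GCCNNNGGC, the site known for AP-2 proteins of other animals, occurred within 100 bp of 24 of 892 summits (2.69%) and in 19 of the paired windows 500 bp away (2.13%). This difference did not pass (exact McNemar p = 0.542), nor did differences of 1.99 points in replicate 2's own list and 1.14 in that of replicate 1 (exact McNemar p = 0.0963 and 0.481). The result depended on the form of the site and on the control: the looser form SCCNNNGGS stood at 11.7% of summits against 5.16% of flanks (exact McNemar p = 1.49e-06), and the form with a longer spacer, GCCNNNNGGC, at 4.15% against 1.46% (exact McNemar p = 0.000936). The palindrome itself passed against the flank on the other side (11 windows, 1.23%, exact McNemar p = 0.041) and within 250 bp (5.16% against 2.91%, exact McNemar p = 0.0225). Against random windows of the same GC content it was 0.336 points less frequent at summits (exact McNemar p = 0.775).

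Of 24 motifs scanned, 9 were more frequent at summits than in flanks and 6 less frequent, at an adjusted p under 0.05. The E2F site TTTSSCGC, bound by cell cycle regulators, stood at 109 summits (12.2%, interval 10.2 to 14.5%) and 23 flanks (2.58%), with an adjusted exact McNemar p of 5.89e-14. The SP1 site GGGCGG occurred at 11.5% of summits and 3.59% of flanks (adjusted exact p = 5.34e-10), and the LAG-1 site of Notch signalling at 10.7% against 6.28% (adjusted exact p = 0.00373). The GAGA, KLF, nuclear receptor half-site and DAF-16 motifs also passed, with differences of 2.69, 2.13, 3.14 and 1.68 percentage points. The nuclear receptor site and DAF-16 passed in neither replicate's own list, and KLF did not pass in that of replicate 1. These 3 also did not pass in the stronger 50% of peaks or in peaks found in both replicates, and GAGA did not pass in the stronger 50% (adjusted exact p = 0.0541). DAF-16 was also lost in the other thresholded list and KLF in single-copy windows (adjusted exact p = 0.0541 and 0.23). Of 3 palindromes with the bases of the AP-2 site in another order, GGCNNNGCC (7.29% against 2.58%) and CGCNNNGCG (5.49% against 1.35%) passed, with adjusted exact p-values of 1.99e-05 and 3.61e-06. In single-copy windows GGCNNNGCC was only 1.9 points more frequent and did not pass (adjusted exact p = 0.158). GATA sites were less frequent at summits (14.1% against 25%, adjusted exact p = 3.87e-08), and so were splice acceptor, T-tract, NF-Y, homeodomain and SKN-1 motifs. Of these, NF-Y and SKN-1 passed in neither replicate's own list, and homeodomain did not pass in that of replicate 1. NF-Y was also lost in the other thresholded list (adjusted exact p = 0.0626). In the stronger 50% of peaks homeodomain and SKN-1 did not pass (adjusted exact p = 0.0541 and 0.47), and in peaks found in both replicates T-tract, NF-Y and SKN-1 did not (adjusted exact p from 0.103 to 0.864). With control windows of the same GC content, a check added after these values were seen, 5 motifs stayed more frequent and 0 less frequent. E2F stood at 12.2% against 4.37% (adjusted exact p = 8.13e-08). LAG-1, GAGA and DAF-16 passed too (each adjusted exact p = 0.0134), as did the permuted palindrome GGCNNNGCC (adjusted exact p = 0.0292). SP1 did not pass, at 11.5% against 8.07% (adjusted exact p = 0.0529, as for CGCNNNGCG). Neither did KLF (adjusted exact p = 0.26) or the nuclear receptor half-site, whose difference was 0.224 points. The GATA deficit shrank to 14.1% of summits against 16.3% of such windows (adjusted exact p = 0.415).

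**Figure D2:**
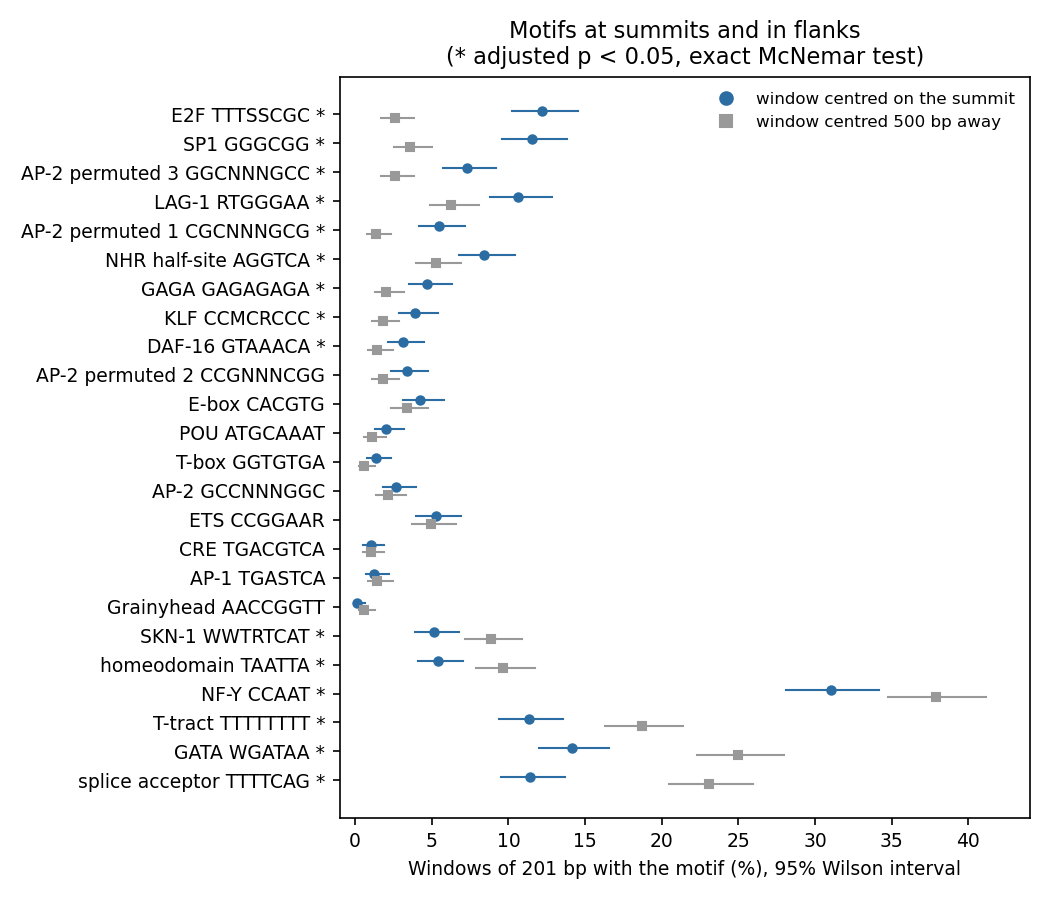
Percentage of 892 windows of 201 bp that held each of 24 motifs, centred on the summit (circles) or 500 bp away (squares), with 95% Wilson intervals; stars mark an adjusted p under 0.05 in exact McNemar tests. E2F sites stand at 12.2% of summits and 2.58% of flanks, and the AP-2 palindrome at 2.69% and 2.13%.

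The next comparison asked which genes carried a summit in their promoter window. This held for 629 of 19973 protein-coding genes (3.15%). Of 24 gene lists fixed before the data were examined, 7 were bound more often than other genes and 1 less often by Fisher's exact test with Benjamini-Hochberg adjustment. Bound means only that a summit lay in the window: without a library lacking the tagged protein, these sites were not told apart from sites that any precipitation recovers. Ribosomal protein genes were bound in 14 of 79 cases (17.7%, interval 10.9 to 27.6%, adjusted exact p = 3.69e-06). They included rpl-35 (III, 7854615 to 7854795, signal 419), rpl-15 (IV, 654850 to 655007, 324), rps-24 (IV, 385475 to 385633, 297) and rps-23 (IV, 12391263 to 12391396, 264). The gene rpl-7A (IV, 194) was bound too, but its name falls outside the pattern fixed for this list, and it is not among the 14. Chaperone and heat shock genes were bound in 11 of 61 cases (18%, interval 10.4 to 29.5%, adjusted exact p = 3.32e-05), among them dnj-28 (239.7), the chaperonin subunit gene cct-7 (180.1), the constitutive Hsp70 gene hsp-1 (147) and dnj-13 (135). Splicing and RNA export genes numbered 11 of 84 (13.1%, interval 7.47 to 21.9%, adjusted exact p = 0.000396), led by prp-19 (444), the nucleoporin genes npp-6 (254) and npp-3 (160.2), and snr-1 (156), which encodes an Sm protein. The prp-19 peak also lay 42 bp upstream of K10D2.5, and the npp-6 window had 50 similar copies in the genome. The respiratory chain list had 7 of 47 genes bound (14.9%, interval 7.41 to 27.7%, adjusted exact p = 0.0025), among them atp-1 (143), atp-5 (114), cox-5B (110.3) and cyc-1 (97.2). This list did not pass in replicate 1's own list, in the stronger 50% of peaks or in peaks found in both replicates (adjusted exact p of 0.401, 0.163 and 0.31), where its ratio to expectation was 2.91, 3.33 and 3.97, against 4.73 in the main list.

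Germline genes were bound in 8 of 45 cases (17.8%, interval 9.29 to 31.3%, adjusted exact p = 0.000396). The strongest were deps-1 (422), which encodes a P granule component, the Argonaute gene csr-1 (239.98), egg-1 (129.6), which acts in fertilisation, and pos-1 (98.2), an RNA-binding regulator of the embryo. The deps-1 peak is also that of its divergent neighbour Y65B4BL.4, and the pos-1 peak that of vha-18. Only 2 of the 8 had a listed peak in both replicates. The list did not pass in either replicate alone, in the stronger 50% of peaks or in peaks found in both replicates (adjusted exact p from 0.112 to 0.31), with ratios to expectation from 3.48 to 4.56 against 5.65 in the main list. Cell cycle and DNA replication genes were bound in 6 of 43 cases (14%, interval 6.56 to 27.3%, adjusted exact p = 0.00738): cdc-25.3 (504), mcm-2 (187), pcn-1 (138) and lin-35 (136), the homologue of the retinoblastoma gene, led them. This list did not pass in replicate 2's own list or in peaks found in both replicates (adjusted exact p = 0.122 and 0.0524), but its ratio to expectation was 4.11 and 6.51 there, against 4.43 in the main list, and these lists are shorter. Histone genes were bound in 10 of 72 cases (13.9%, interval 7.72 to 23.7%, adjusted exact p = 0.000396), at 6 distinct peaks, since divergent neighbours such as his-63 and his-64 (IV, 11406936 to 11407028, 251) share a summit; his-42 (227), whose window had 20 similar copies and an snRNA gene nearby, and his-61 (189.8) followed. Histones no longer passed in a permutation within deciles of promoter GC content (adjusted permutation p = 0.203, ratio 1.88 against 4.41), nor did the cell cycle list (adjusted permutation p = 0.0542, ratio 3.42). When each summit was given only to its nearest start within 2000 bp, the germline list alone passed (7 of 45, adjusted exact p = 0.0116); 6 other lists, with the nuclear hormone receptors among them, stood at an adjusted exact p of 0.0546. Under this rule the ratio to expectation fell from 5.63 to 2.8 for ribosomal proteins (7 bound), from 5.73 to 3.11 for chaperones (6 bound), from 4.41 to 3.08 for histones and from 4.16 to 2.26 for splicing and RNA export (6 bound, adjusted exact p = 0.149). In peaks found in both replicates, under the main rule, these ratios were higher, at 10.6, 10.7, 9.07 and 5.56 in the same order, and each list passed. In single-copy windows the histone ratio was lower than in the main list, at 3.11.

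Nuclear hormone receptor genes were bound less often, in 1 of 274 cases (0.365%, interval 0.0645 to 2.04%, adjusted exact p = 0.00787), the member being nhr-119 (87.5). This call was lost in the other thresholded list, in each replicate's list, in peaks found in both replicates and with the nearest start (adjusted exact p from 0.0526 to 0.379), although the ratio to expectation, 0.116 in the main list, stayed at 0.238 or less. Of 225 cuticle and collagen genes 2 were bound, col-71 (84.2) and col-63 (82.3), which did not pass (adjusted exact p = 0.139). Epidermal regulators had 1 of 18 genes bound, lin-26 (75.9), a zinc finger gene of epidermal fate, with its summit in a coding exon (II, 7681884 to 7682179; adjusted exact p = 0.809). The counts were 1 of 20 for pan-neuronal genes (ehs-1, 86.1), 1 of 32 for muscle (act-2, 99.1), 1 of 91 for homeobox genes (ceh-83, 103.9), 2 of 33 for the proteasome (pbs-3, 97.5, and rpn-11, 93.3) and 2 of 20 for the vacuolar ATPase (vha-18, 98.2, and vha-13, 81.1). Epidermal junctions and cytoskeleton (20 genes), ventral enclosure signalling (21), neuronal identity (27), major sperm proteins (31), intestine (27), pharynx (13), helix-loop-helix factors (39) and the Wnt pathway (27) had 0 bound genes, as had the AP-2 family, and none of these passed. Upper limits of the Wilson interval for these 9 lists ran from 8.97% to 49%.

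**Figure D3:**
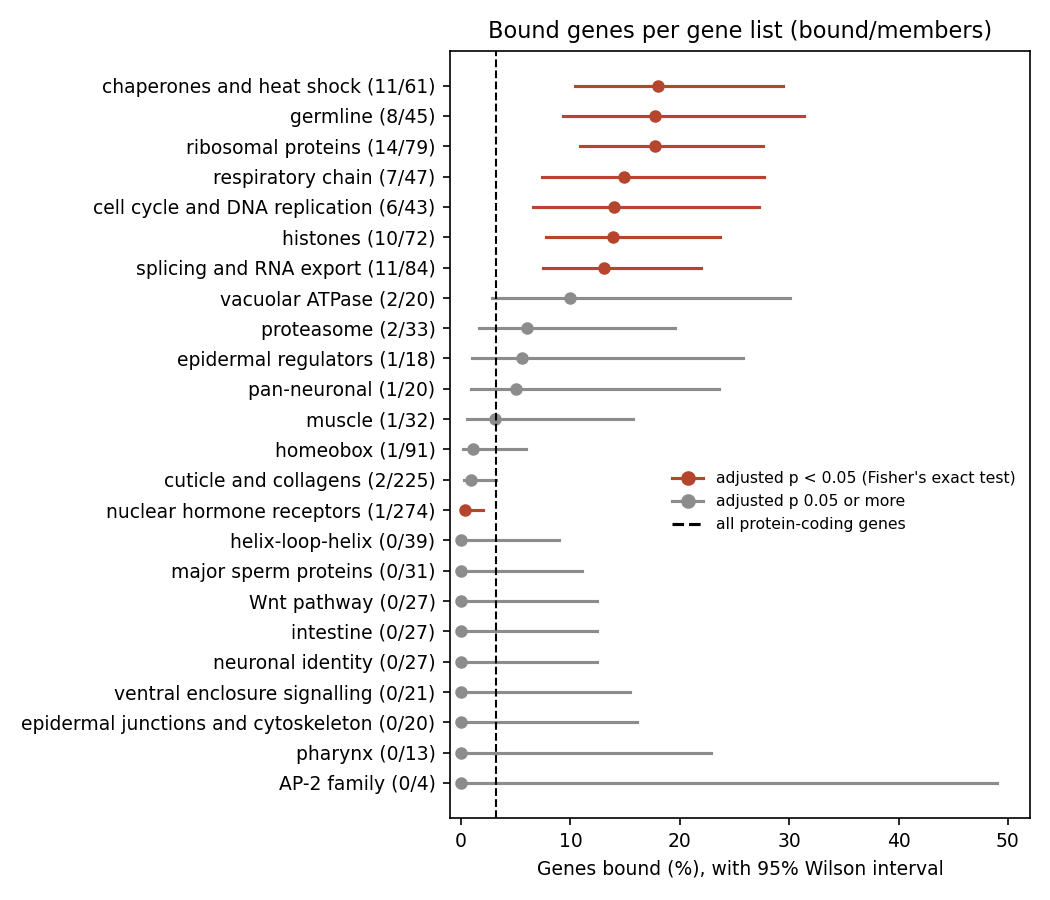
Percentage of genes with a summit in the promoter window for each of 24 gene lists, with 95% Wilson intervals; coloured points have an adjusted p under 0.05 in Fisher's exact tests, and the dashed line marks the 3.15% of all protein-coding genes. Chaperone, germline and ribosomal protein genes stand near 18%, and nuclear hormone receptors at 0.365%.

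Summits also lay near genes for small non-coding RNAs. Within 200 bp of a tRNA gene there were 72 of 892 summits (8.07%, interval 6.46 to 10%), against 0.25% at random positions, or 32.3 times as many. This ratio was 24 in replicate 2's own list, 18.6 in that of replicate 1 and 8.46 in peaks found in both replicates, and each passed. Near snoRNA genes, whose products guide the modification of other RNAs, the count was 47 (5.27%, 26.8 times). Near genes of the spliceosomal snRNAs it was 42 (4.71%, interval 3.5 to 6.3%, 73 times). In summit windows with a single copy in the genome only 9 of these 42 remained and the ratio was 22.1, under that of snoRNA (34.7) and tRNA (31.6). A copy here means a match of 100 bp or more, longer than many of these genes, so copies of the gene alone pass this filter. With matches of 30 bp or more counted, unrepeated windows numbered 3 of 72 for tRNA, 35 of 47 for snoRNA and 5 of 42 for snRNA. The order of the 3 classes therefore depends on the filter. The annotation's broader class of ncRNA genes had 145 summits nearby (16.3%, 4.86 times). Each of these classes had an adjusted two-sided permutation p of 0.003, the smallest that this number of placements and classes gives here. For miRNA genes 4 summits (0.448%, 3.85 times, adjusted permutation p = 0.0456) were near, a call that was lost at 50 bp and in peaks found in both replicates (adjusted permutation p = 0.134 and 0.0527). The miRNA ratio was 8.39 in replicate 2's own list, 7.39 in that of replicate 1 and 7.53 in the stronger 50% of peaks, and each passed. None lay near rRNA genes, which allows a share of up to 0.429%. The strongest tRNA-linked peak was on III at 11066849 to 11067000, in an intron and 9 bp upstream of WBGene00014553, with a signal of 262 and 3 similar copies of its window, itself included. For snoRNA the strongest were on I at 10517145 to 10517326 (309) near F59C6.15 and on II at 10065714 to 10065854 (286) near C18D1.21. For snRNA they were on I at 12173642 to 12173821 (327) and at 12286689 to 12286864 (307), near WBGene00014483 and WBGene00014403; each of these windows had 20 similar copies in the genome. The strongest of the miRNA class was near cel-mir-4932 (I, 9512232 to 9512527, 198), followed by cel-mir-51 (IV, 11026034 to 11026329, 139). Of the ncRNA class, the peak on IV at 4725505 to 4725684 lay 143 bp upstream of WBGene00195021.

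**Figure D4:**
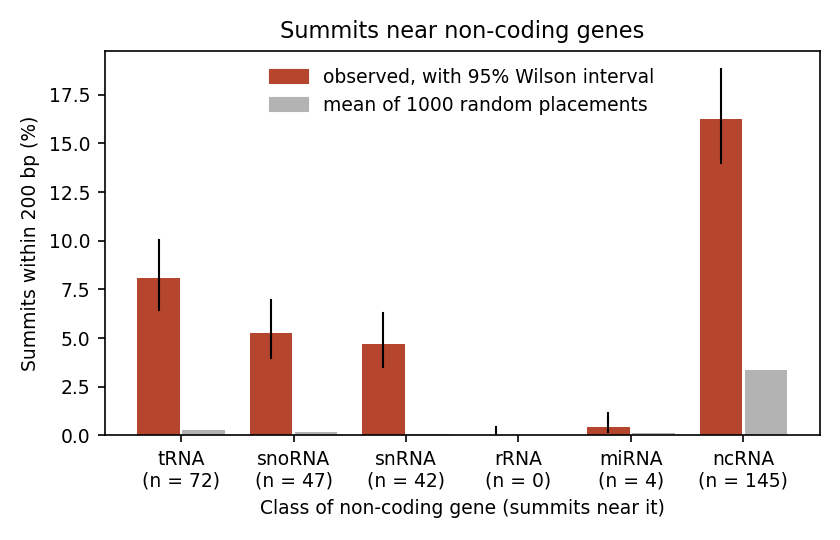
Percentage of the 892 main-list summits within 200 bp of each class of non-coding gene (coloured bars, with 95% Wilson intervals) and the mean of 1000 random placements (grey bars). tRNA genes stand at 8.07% against 0.25% at random.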

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

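The test of copies in this part was chosen after the peaks had been found and before its own result was seen. The comparison of paired replicate signals was chosen after the peaks had been found. The overlap test took its present form after a first count had been seen. The ranked list behind the main list held 58 peaks that passed the IDR limit of 0.01 but were absent from the main list, and these data enter no comparison above. The highest signal among them was 2408.92, on X at 15810950 to 15811171, between genes and 6936 bp upstream of the nearest protein-coding start, that of Y7A5A.7. This was 2.54 times the highest signal of the main list, and both replicates had it in their own ranked lists (1323 and 1246). The next were on V at 16708871 to 16709051 near clec-9 (834), on X at 11785775 to 11785888 near Y102F5A.1 (626) and on IV at 9047436 to 9047515 near Y73F4A.1 (604). Only 2 of the 58 (3.45%) lay in a promoter window, against 55.3% of the main list.

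Both technical explanations looked at went with the data. For the overlap the rule was set after a first count was seen, so it is no independent test. None of the 58 (0) overlapped a peak of the 3 thresholded lists other than the main list, from which they are absent by choice. Of the main-list peaks 732 of 892 (82.1%) did. This would be seen if the same regions were left out of each list. A second copy of the summit window stood elsewhere in the genome for 54 of 58 (93.1%), against 207 of 892 main-list windows (23.2%; Fisher's exact test, p = 9.67e-28), and the window of the strongest had 195 copies. This test counts peaks as independent, but the 58 fell into 37 separate regions. The replicate signals paired in the ranked list also differed more at these peaks. The SD of the log2 ratio between them was 1, against 0.39 in the main list. A candidate explanation is that reads from repeated sequence pile up at these sites and that the authors' lists leave such regions out. Which regions were left out, and by what rule, is not given in the sources used here, and no biological explanation was tested.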

How the results depend on the processing

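Alternatives added after the data were seen are 1 peak per pair of replicate peaks, single-copy windows and GC-matched controls of the motif scan. Replicate overlap, rank agreement and promoter share kept their direction and passed under each alternative run, with overlap from 51.6 to 80.6%, rho from 0.579 to 0.815 and a promoter excess from 23.6 to 40.1 points. The X to autosome density ratio ran from 0.584 to 0.768 with 1 replicate left out, did not pass in replicate 2's list and passed under each other alternative run. The central excess on autosomes, 5.4 points, was 0.867 to 4.98 points with 1 replicate left out, 4.29 in the stronger 50% of peaks and 0.962 in peaks found in both replicates; none of these passed, and each list was shorter. The AP-2 palindrome excess of 0.561 points did not pass, nor did 1.14 to 1.99 with 1 replicate left out, but it became 2.24 within 250 bp, 6.5 as SCCNNNGGS, 2.69 as GCCNNNNGGC and 1.46 against the flank on the other side, which passed, and turned to -0.336 against windows of the same GC content. Motifs more frequent at summits numbered 9; there were 5 in the stronger 50% and 5 with GC-matched windows. Motifs less frequent, 6, fell to 3 to 4 with 1 replicate left out, 3 in peaks found in both replicates and 0 with GC-matched windows, where the homeodomain (1.68 points) and T-tract (2.35 points) differences turned positive. Lists bound more often, 7, became 4 in peaks found in both replicates and 1 with the nearest start. Lists bound less often, 1, became 0 in the other thresholded list, 0 with either replicate left out, 0 in peaks found in both replicates and 0 with the nearest start. Some of these lists are shorter; otherwise the cause was not tested. Single motifs, lists and classes kept their call in 192 cases, lost it in 61 and turned in 2; of 77 named peaks, 62 were present in replicate 1's list and 62 in replicate 2's. Depth is unknown, so what it limits cannot be given.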

Other observations

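The tests in this part on name families, short sequences, copies of the non-coding genes, their share among strong peaks and neighbouring peaks were chosen after the results they bear on were seen. The GC content tests were chosen before their own results, but the 200 repeated draws for the AP-2 forms were added after a first draw had been seen. Among 240 families of genes with the same name stem and at least 8 members, 8 were bound more often than other genes and 0 less often (Fisher's exact test, Benjamini-Hochberg adjusted). Beside ribosomal, heat shock and histone families these were nucleoporin genes (npp, 6 of 26, adjusted exact p = 0.00614), translation initiation factor genes (eif, 5 of 25, adjusted exact p = 0.0346), cytochrome c oxidase genes (cox, 4 of 15, adjusted exact p = 0.0346) and mcm genes (3 of 8, adjusted exact p = 0.0464). The mcm members were mcm-2 (signal 187) and mcm-10 (103.1), which act in DNA replication, and mcm-3AP (209), which is not a subunit of the MCM helicase. The mcm call counts mcm-3AP, and whether the family passes without it was not tested. Members npp-3, npp-6, cox-5B and mcm-2 are named above under other lists, so these families are not independent of them. None of the 4 cox peaks overlapped a peak of either replicate's own thresholded list. The cox-6A window had 19 similar copies, itself included, and an snRNA gene nearby. The families were tested in the main list only and not under the nearest-start rule. The eif members were eif-3.B (signal 114), eif-3.E (106.8), eif-3.G (99.9), eif-2Bgamma (96.4) and eif-3.I (95.8). The chemoreceptor family str had 0 of 193 genes bound, where 6.08 were expected, and did not pass (adjusted exact p = 0.0861).

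A search of 8-base sequences on chromosomes I, III and V gave 10 sequences, each of which also passed on II, IV and X. A scan of all chromosomes had already shown the sequence TCCCAGGA, so II, IV and X were not untouched data. TCCCAGGA, picked from the 10 for its tie to strong peaks, stood at 43 of 892 summits and 1 flank. This excess passed when adjusted for all 32896 possible sequences of that length (Bonferroni-adjusted exact McNemar p = 1.68e-07), which argues against a chance find. On II, IV and X it stood at 19 of 438 summits and 0 flanks (exact McNemar p = 3.81e-06), and peaks with it had a median signal of 177, against 102 for the other peaks. Having been picked for strong peaks, it has no independent test of this. Over all chromosomes it occurred in 10 of the 25 strongest peaks, in 31 of the strongest 223 (13.9%) and in 12 of the other 669 (1.79%). Of its 52 sites in the summit windows 46 (88.5%) lay within 50 bp of the summit, where 52.1% would with even spread (exact binomial p = 3.29e-08), and it held in single-copy windows (28 summits against 1 flank, exact McNemar p = 1.12e-07). That last test took in all chromosomes, also those searched, so it is not independent. The same search run on single-copy windows alone did not keep this sequence among its 10. A hypothesis is that this sequence may be part of a site for the tagged protein or for another factor at these peaks; only 52 of its 1514 sites in the genome lie in main-list summit windows, and binding itself was not tested. GCGCGAAA, which overlaps the E2F site, stood at 22 tested summits and 1 flank (exact McNemar p = 5.72e-06), and GACGCAGA at 25 and 4 (exact McNemar p = 0.000104), with no higher signal that passed (adjusted permutation p = 0.247 and 0.94).

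The looser forms of the AP-2 site raise the question of GC content, since summit windows had a median GC of 45.3%. SCCNNNGGS stayed more frequent than in GC-matched windows, by 3.14 points (exact McNemar p = 0.0381), and 0 of 200 further draws of such windows had it as often. GC content alone is therefore unlikely to give its whole excess. For GCCNNNNGGC the difference was 0.785 points (exact McNemar p = 0.45), and for the palindrome within 250 bp 1.12 points (exact McNemar p = 0.314), and 13 and 5 of 200 draws had them as often, so for these GC content stays open. Single draws differ by chance. The permuted palindromes GGCNNNGCC and CGCNNNGCG were more frequent than in flanks, and GGCNNNGCC also stayed more frequent than in GC-matched windows, by 3.14 points as SCCNNNGGS did (adjusted exact p = 0.0292), but did not pass in single-copy windows (adjusted exact p = 0.158). CGCNNNGCG passed in single-copy windows (4.38 points) and not against GC-matched windows (adjusted exact p = 5.55e-05 and 0.0529). An excess over flanks was therefore also seen with other orders of the bases of the strict palindrome. No permuted form of SCCNNNGGS was scanned, so whether its excess is particular to its order of bases was not tested. No biological explanation was tested.

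Summits near tRNA, snoRNA and snRNA genes were weighed against shared reads and base composition. A copy of 100 bp is longer than many of these genes, so shared reads were tested on summits whose window and nearby gene had no stretch of 30 bp or more at 90% identity or more elsewhere in the genome. The rule for reading this test, with the spread of the count, was set after a first run had been seen. The random positions were drawn without this filter on their own windows, so the ratios of this test are not like for like and can be too high. For snoRNA 29 summits remained, 58.8 times the number at random positions (exact Poisson limits 39.4 to 84.5, permutation p = 0.002). These 29 lay where neither window nor gene had such a stretch elsewhere, so reads shared between copies are not the whole cause there. For tRNA only 5 of 612 genes had no such stretch and 0 summits remained, and for snRNA 15 of 129 genes and 1 summit (47.6 times, exact Poisson limits 1.21 to 265). These counts are too few to decide, so shared reads stay open for both. Against positions of the same GC content the excess was 16.9, 16.7 and 33.6 times, above each of 200 draws. This argues against GC content as the whole cause. The ratios were lower than the 32.3, 26.8 and 73 against random placement, so a part for GC content stays open. Peaks near tRNA genes were scarce among the strongest, with 4 of 223 in the strongest 25% of peaks and 68 of 669 in the rest (Fisher's exact test, p = 1.33e-05). Their median signal of 97.4 was close to the 102.9 of the main list. A recovery of much transcribed chromatin by any precipitation may explain the excess and stays open, since no library without the tagged protein was analysed here.

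The main list held 38 peaks with a signal under 60, down to 2.59. Of these, 36 were matched to the same pair of replicate peaks as a stronger neighbour, at a median of 202 bp between summits; their median signal was 9.73, against 95.4 for the neighbours. The lowest signal of any other main-list peak was 51.6.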
